A study of Arabidopsis thaliana with 2 samples.

How the data were processed

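Messenger RNA was measured by RNA sequencing in whole rosettes of untreated Arabidopsis thaliana plants of the Col-0 accession at 28 days of age. There were 2 libraries, 1 from wild type plants and 1 from a pbl19 null mutant carrying a PBL19 transgene in which cysteine 3 is replaced by alanine (C3A), fused to green fluorescent protein and a haemagglutinin tag and driven by the PBL19 promoter. The wild type group was taken from its genotype label and the C3A group from its sample title. How many plants went into each library was not given in the sources used here. RNA was extracted with a phenol-based reagent and sequenced as 150 bp paired-end reads on a BGI instrument, per the labels' protocols.

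The reads were trimmed and aligned before deposit. Trimmomatic 0.36, HISAT and the TAIR10 genome are named in the submitters' processing notes, while the HISAT version, the quantification tool and whether counting used strand were not given in the sources used here. Each deposited table lists genes with an estimated (expected) count, a gene length and an FPKM, per the file headers. FPKM is a count scaled to gene length and to the fragments counted in the library. The deposited estimated counts were whole for 89.1% of listed wild type genes and 88.9% of listed C3A genes (tolerance 1e-09), and the remainder were fractional, as happens when reads matching several genes are divided between them. The deposited FPKM values were not scaled further for the main comparison, and the gene lengths deposited by the authors were used as they stand. For genes with several transcripts the deposited length differed between the libraries. All 12079 genes with a single transcript had the same length as the reference transcript (tolerance 0.01). Both tables list only genes above 0. For the wild type 22310 genes and 11937705 counts were listed, and for the C3A line 22564 genes and 12001808 counts. Of the 23147 genes listed in either library, 21727 were listed in both, and a gene listed in 1 library was set to 0 in the other.

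Names, product descriptions and coordinates come from the RefSeq annotation of TAIR10.1. Of the 23147 identifiers, 22970 were found there and 177 were not. Coordinates are given on TAIR10.1 and were not taken from the deposited tables. Of the 119 genes the naming rule gives, 32 overlap another annotated gene, 30 of them on the opposite strand. Since the use of strand in counting is not known, the values of these genes are uncertain.

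The difference between the libraries was the log2 ratio of FPKM + 1, C3A over wild type, for the genes with an FPKM of at least 1 in either library. Ratios on this scale understate the difference of genes with low FPKM. With 1 library per genotype there was no replicate check, no test between genotypes and no p-value. Genes with a ratio of at least 2-fold in either direction were counted as a description of these libraries. A fold given for a single gene is the plain ratio of its FPKM values, with the exact conditional (Clopper-Pearson) 95% interval of its rounded estimated counts carried over to the FPKM ratio. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules and plants differ. No fold is given against an unlisted gene.

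Before the data were examined, 26 gene lists with 390 genes in all were written down. For each list with at least 3 members at an FPKM of at least 1, the median log2 ratio was set against the medians of 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile is a description of these libraries. The 95% interval of a median comes from its order statistics, or is the whole range of a list with under 6 members, and treats genes as independent. Families named by reference description, and genes encoded in the chloroplast or mitochondria, were treated in the same way. Setting unlisted genes to a floor of 3 counts left the median of each of these lists as it was to 2 decimals. The genes named were PBL19 and PBL20, the 12 genes with the largest positive and the 12 with the largest negative log2 ratio among those with an FPKM of at least 10 in the higher library, up to 4 members of each list by the size of the ratio, and PR1, PR2, PR5, EDS1, PAD4, ICS1 and FMO1 in any case. This rule was also fixed before the data were examined.

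The calculations used python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for trimmed mean of M values (TMM) factors, which served an alternative only. The steps were tested on simulated data. Counts were drawn for 19247 genes from the levels of these libraries with 200 genes changed, each with a mean of at least 20 counts. The draws held counting error only and no variation between plants, so the rates below do not cover such variation. Past the 2-fold threshold were 22% of genes simulated at 2-fold, 100% at 4-fold and at 8-fold, 92% at 0.25-fold and 0.0998% of unchanged genes. The 95% intervals held the simulated ratio for 96% to 100% of genes. A planted list of 15 genes at 2-fold reached percentile 100, and 7 of 100 unchanged lists lay outside the central 95% of matched random lists.

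The alternatives tried were pseudocounts of 0.1 and 5, no filter, an FPKM minimum of 5, FPKM rescaled to a median ratio of 1, FPKM rescaled after leaving out the 100 most abundant genes, estimated counts as CPM with TMM scaling and a prior of 1 CPM, a 4-fold threshold, and random lists matched on the wild type level. Restriction to genes with whole counts and to genes of at least 500 bases was added after seeing the data, and so were the values of the PBL19 subgroup without PBL19 and without PBL20.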

Results

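The transcriptome of 28-day-old rosettes was compared between wild type Arabidopsis (Col-0) and a pbl19 null mutant that carried the tagged transgene PBL19 C3A, in which cysteine 3 of the kinase is replaced by alanine. PBL19 is a receptor-like cytoplasmic kinase, a class of kinases that relay signals from immune receptors at the cell surface. Cysteines near the start of such kinases can carry a lipid that holds the protein at the plasma membrane. The comparison asks which genes differ in expression between the transgenic line and the wild type in the absence of any treatment. There was 1 library per genotype, with 11937705 estimated counts for the wild type and 12001808 for the C3A line, so no value has a replicate check and every difference is one between these libraries. The libraries differ in the null allele, the C3A change, the tags and the PBL19 level together. A line carrying the unchanged PBL19 transgene was not analysed here. Where a pair of FPKM values is given for a gene, the first is the wild type and the second the C3A library.

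PBL19 (AT5G47070) itself was 69.7-fold higher in the C3A library (95% counting interval 59.7 to 81.9), at 6.68 FPKM from 163 counts in the wild type and 466 FPKM from 11419 counts in the C3A line. The gene lies on the minus strand of chromosome 5 at 19118465 to 19121103 (TAIR10.1), has 4 exons and encodes 410 amino acids that begin MNCLFLFKSK. Its coding sequence starts ATGAACTGTCTGTTCTTGTTCAAATCAAAG. Codon 3, TGT for cysteine, lies at 19120520 to 19120522 on chromosome 5 and is the codon the transgene replaces. The tables count reads per gene, so they do not tell reads of the transgene from those of the native locus, and PBL19 overlaps AT5G47060 on the opposite strand. Of the 5 other members of its kinase subgroup, 4 were at least 2-fold higher as deposited and 3 after each rescaling, with a median log2 ratio of 1.36 as deposited. Without PBL20 as well, the counts were 3 and 2 of 4. The list as fixed, which counts PBL19 itself, had 5 of 6 higher and a median of 1.43 (95% interval -0.72 to 5.92), to which the transgene's own gene contributes. PBL39 was at 4.83 FPKM in the wild type and 18.9 in the C3A line. PBL37, with fractional counts, was at 6.56 and 18.5. PBL38, named after its value was seen, was lower, at 4.77 and 2.51 FPKM. PBL20, the nearest relative, was at 0.05 and 1.94 FPKM from 1 and 38 counts, a ratio of 38.8 with a counting interval of 6.56 to 1572. Its transcript shares 4 stretches of 31 bases with PBL19.

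Differences of at least 2-fold were found in 1541 genes higher and 557 genes lower in the C3A library, out of 19527 genes with at least 1 FPKM in either. The counting interval, carried over to the FPKM + 1 scale, lay wholly past 2-fold for 764 of the higher and 279 of the lower genes. Genes unlisted in 1 library have no such interval and are not among them. The median gene was 0.14 higher on the log2 scale in the C3A library, a shift against which the ratios below are to be read. Higher genes made up 73.5% of these differences as deposited and 61.6% (1236 higher and 770 lower) after rescaling to a median ratio of 1. The share was 61.2% (1228 and 780) after rescaling without the 100 most abundant genes and 59.9% (1299 and 868) with TMM-scaled counts. A few genes took a larger share of the wild type library, where the 100 most abundant genes held 28.2% of counts against 21.04% in the C3A library.

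**Figure D1:**
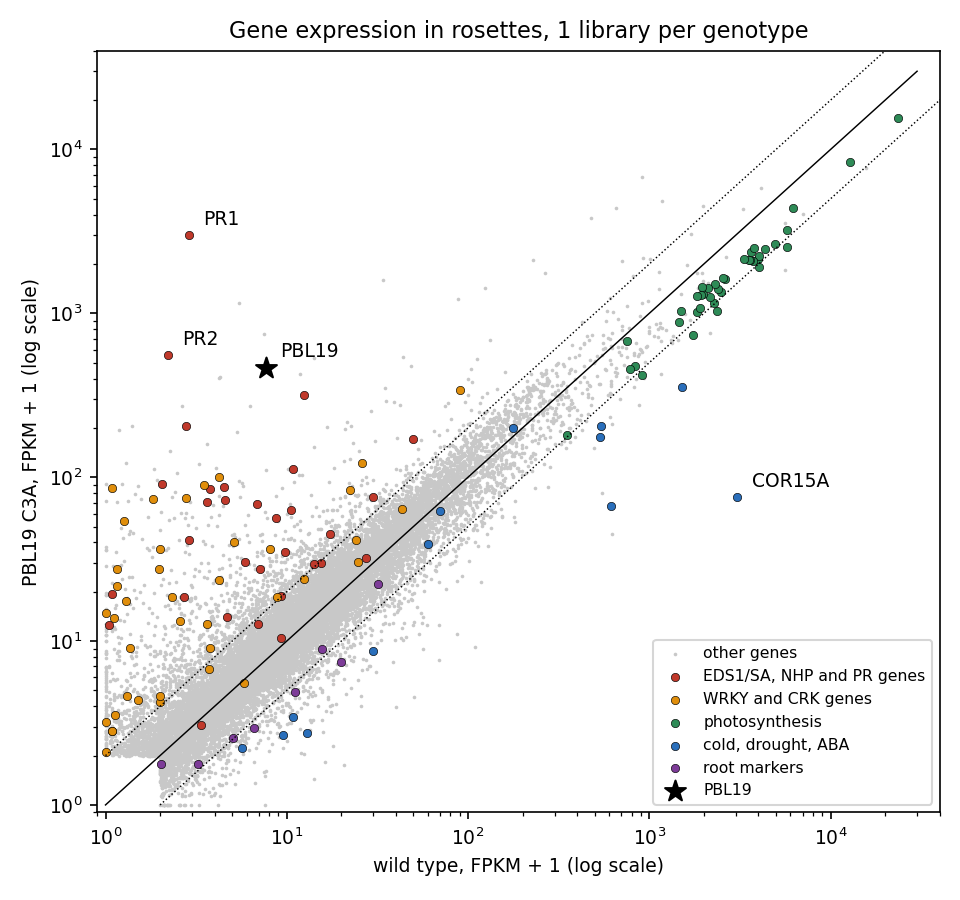
FPKM + 1 of each compared gene in the wild type library (x axis, log scale) and the PBL19 C3A library (y axis, log scale), 1 library per genotype, with members of gene lists in colour, PBL19 as a star, the line of equality drawn solid and 2-fold differences dotted. PR1 (1.88 and 2986 FPKM) and PBL19 (6.68 and 466 FPKM) lie far above the lines and COR15A (3044 and 74.8 FPKM) far below, while photosynthesis genes lie at the upper right below the line of equality.

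PR1, a secreted antimicrobial protein and the standard marker of salicylic acid responses, had the largest ratio of the named genes, at 1.88 FPKM in the wild type and 2986 FPKM in the C3A library. It was 1588-fold higher (counting interval 1028 to 2601). PR2, a glucanase, was at 1.21 and 553 FPKM, 457-fold higher (289 to 771). PCR1, a plasma membrane protein named for cadmium resistance, was at 4.43 and 1163 FPKM. AIG1, first described as induced by a bacterial effector, was at 0.40 and 203 FPKM. The glucanase BG3 was at 0.30 and 122 FPKM, and the aspartyl protease AT5G10760 at 3.29 and 408 FPKM. The acireductone dioxygenase ARD3 was at 0.19 and 192 FPKM, the wild type value resting on 2 counts. AT4G22510, AT4G22513 and AT4G22517, of which the last pair encodes lipid-transfer proteins, were at 6.51, 1.65 and 3.22 FPKM in the wild type and at 744, 269 and 400 FPKM in the C3A library. AT4G22510 overlaps the other pair on the opposite strand, and AT4G22513 and AT4G22517 have fractional counts in the C3A library (1975.15 and 2880.85). Reads of these genes therefore cannot be assigned to single genes with certainty, and their ratios may not be separate results. AT1G64795, a gene of 201 bases that overlaps AT1G64790, was not listed in the wild type and reached 90.2 FPKM in the C3A library. CRK6, a cysteine-rich receptor-like kinase with counts shared with other genes, was at 0.09 and 85.1 FPKM.

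The EDS1 and salicylic acid pathway was higher as a group, with 18 of 22 members at least 2-fold higher, none at least 2-fold lower and a median log2 ratio of 2.48 (95% interval 1.34 to 3.99). EDS1, a lipase-like hub of immune receptor signalling, was 6.53-fold higher (5.71 to 7.49), at 9.51 and 62.1 FPKM. Its partner PAD4 was 11.2-fold higher (9.92 to 12.8), at 9.85 and 111 FPKM. ICS1, the isochorismate synthase that makes most of the salicylic acid in infected leaves, was 11.6-fold higher (9.81 to 13.8), at 5.85 and 68.0 FPKM. DLO1 and DMR6, enzymes that hydroxylate salicylic acid, were at 1.05 and 11.4 FPKM in the wild type and at 89.8 and 318 FPKM in the C3A library. NIMIN1 and NIMIN2, which bind the salicylic acid receptor NPR1, were at 2.64 and 2.78 FPKM against 69.6 and 84.1 FPKM. All 4 members of the N-hydroxypipecolic acid pathway, which makes a mobile signal of systemic immunity, were at least 2-fold higher, with a median of 3.13. FMO1 was at 0.09 and 18.4 FPKM from 2 and 426 counts and ALD1 at 0.05 and 11.5 FPKM from 1 and 218 counts. SARD4, which overlaps AT5G52800 and has fractional counts, was at 7.72 and 55.1 FPKM. UGT76B1, which glucosylates the product, was at 8.28 and 17.9 FPKM. Its log2 ratio of 1.03 was 0.89 after rescaling to a median ratio of 1, under 2-fold. Of the 5 pathogenesis-related proteins 4 were at least 2-fold higher, with a median of 6.21. PR5 was at 1.77 and 204 FPKM and PR4 at 48.9 and 169 FPKM. The medians of these 3 lists lay above those of all 10000 matched random lists.

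**Figure D2:**
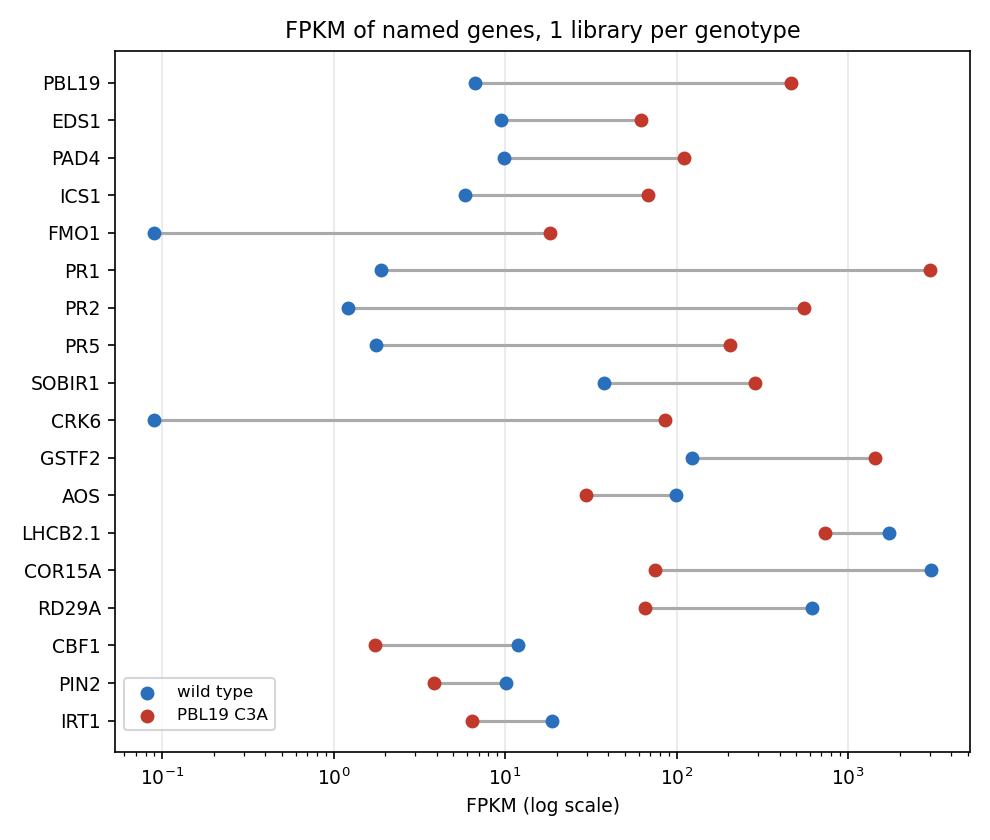
FPKM (x axis, log scale) of 18 named genes in the wild type library (blue points) and the PBL19 C3A library (red points), 1 library per genotype, with a line joining the values of each gene. EDS1 (9.51 and 62.1 FPKM), PAD4, ICS1 and the pathogenesis-related genes lie to the right in the C3A library, and AOS, LHCB2.1, COR15A, RD29A, CBF1, PIN2 and IRT1 (18.8 and 6.42 FPKM) lie to the left.

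Among cysteine-rich receptor-like kinases 15 of 17 were at least 2-fold higher, with a median log2 ratio of 2.37 (1.27 to 3.90), above all 10000 random lists. CRK45 was at 0.83 and 72.1 FPKM, CRK4 at 3.23 and 98.97 FPKM, and CRK7, whose counts are partly shared, at 0.15 and 26.7 FPKM. The pattern-triggered immunity list had 6 of 17 members at least 2-fold higher and a median of 0.80, above 9999 of the 10000 random lists. Those named were RLP23, the receptor for a peptide of NLP toxins (0.46 and 77.9 FPKM, partly shared counts), and SOBIR1, its co-receptor kinase (38.0 and 288 FPKM). They also included FRK1, a kinase used as a marker of flagellin responses (0.21 and 9.38 FPKM), and the MAP kinase MPK11 (0.93 and 12.9 FPKM). CRK45, RLP23, SOBIR1 and FRK1 overlap genes on the opposite strand, so their reads are not assigned with certainty. Among WRKY transcription factors 19 of 23 were at least 2-fold higher and the median was 1.91 (1.38 to 2.97), above all 10000 random lists. WRKY38 was at 0.26 and 52.9 FPKM, WRKY51 at 1.79 and 73.3 FPKM, WRKY18 at 2.48 and 88.0 FPKM, and WRKY62 at 0.16 and 20.6 FPKM. Intracellular NLR immune receptors had 4 of 21 at least 2-fold higher and a median of 0.56 (0.24 to 0.72), at percentile 99.94. One was TN2, which was unlisted in the wild type and at 2.90 FPKM in the C3A library. CHS1 (1.81 and 9.38 FPKM) and its neighbour SOC3 (1.60 and 6.94 FPKM) overlap. VICTR, with fractional counts, was at 5.38 and 12.9 FPKM, and its log2 ratio was 1.12 as deposited and 0.99 after rescaling to a median ratio of 1.

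For camalexin and indole glucosinolates, sulfur-containing defence compounds made from tryptophan, 10 of 15 genes were at least 2-fold higher and the median was 1.5 (0.41 to 2.01). PAD3, the last enzyme of camalexin synthesis, was at 2.2 and 15.9 FPKM, and the regulator MYB51 was at 5.88 and 34.2 FPKM. CYP71A12 and CYP71A13, closely related enzymes with fractional counts, were at 2.85 and 1.46 FPKM in the wild type and at 37.0 and 8.92 FPKM in the C3A library. All 17 genes for folding and secretion in the endoplasmic reticulum lay above 0, with a median of 1.15 (0.90 to 1.73). Of them 12 were at least 2-fold higher as deposited and 8 after rescaling to a median ratio of 1. The calreticulin CRT3 was at 34.1 and 291 FPKM, the chaperone BIP3 at 0.16 and 4.89 FPKM, the nucleotide sugar transporter UTR1 at 4.85 and 23.3 FPKM, and TIN1 at 0.29 and 4.06 FPKM. In the detoxification and oxidative stress list, 10 of 18 genes were at least 2-fold higher and 1 was at least 2-fold lower, with a median of 1.76 (-0.10 to 3.12). The glutathione transferases GSTF2, GSTF6 and GSTF7, each with fractional counts in at least 1 library, were at 123, 33.7 and 20.4 FPKM in the wild type and at 1430, 350 and 218 FPKM in the C3A library. BAP2, an inhibitor of cell death, was at 0.10 and 27.8 FPKM from 1 and 293 counts. Of 13 leaf senescence genes 7 were at least 2-fold higher and 1 lower, with a median of 1.02 (-0.07 to 1.83). SAG13 was at 0.80 and 31.7 FPKM, SAG21 at 131 and 681 FPKM, the asparagine synthetase ASN1 at 16.8 and 62.2 FPKM, and the regulator ORE1 at 3.13 and 10.7 FPKM. Of the genes named here, CYP71A13, GSTF2, SAG21 and ASN1 overlap other genes. The medians of the lists in these sentences lay above those of all 10000 random lists.

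The median of the jasmonate and ethylene list did not stand apart, but its members went both ways, 8 above 0 and 6 below, from -1.72 to 1.74. A central median of such a mixed list does not mean that its genes did not differ. Of 14, 1 was at least 2-fold higher and 1 lower. The median of 0.15 (-0.75 to 0.81) lay at percentile 46.7 of the random lists and changed sign, to -0.06 with TMM-scaled counts and to -0.32 over genes with at least 5 FPKM. AOS, which commits fatty acids to jasmonate synthesis, was 3.36-fold lower in the C3A library (3.09 to 3.66), at 99.6 and 29.6 FPKM. The storage protein VSP1, with fractional counts, was at 38.9 and 20.2 FPKM, while the ethylene response factors ERF1 and ORA59 were at 0.09 and 1.94 FPKM in the wild type and at 2.64 and 4.71 FPKM in the C3A library.

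Genes of the cold, drought and abscisic acid list were lower in the C3A library, with 10 of 13 members at least 2-fold lower, none higher and a median log2 ratio of -1.65 (-2.23 to -0.63), below all 10000 random lists. COR15A, a chloroplast protein that protects membranes during freezing, was 40.7-fold lower (37.9 to 43.8), at 3044 FPKM in the wild type and 74.8 FPKM in the C3A library. RD29A was 9.40-fold lower (8.99 to 9.83), at 614 and 65.4 FPKM, and COR6.6 was at 1505 and 353 FPKM. CBF1, a transcription factor that induces these genes in the cold, was at 11.9 and 1.75 FPKM. The other genes with the largest negative ratios were COR15B at 618 and 44.0 FPKM, GolS3 (galactinol synthesis) at 39.3 and 2.98 FPKM, and AT1G51090 at 108 and 8.19 FPKM. Further ones were AT1G70640 at 19.6 and 0.75 FPKM, AT3G28220 at 49.1 and 3.55 FPKM and AT3G27250 at 17.0 and 1.28 FPKM. They also included the terpene synthase TPS03 at 13.1 and 0.44 FPKM, the jasmonate-responsive aminotransferase-like gene CORI3 at 68.1 and 6.69 FPKM, SQP1 at 15.3 and 0.84 FPKM and the cytosolic fumarase FUM2 at 86.3 and 10.04 FPKM. The circadian clock list was measured because many cold genes follow the time of day. On the FPKM + 1 scale it had 1 of 17 members at least 2-fold lower, none higher and a median of -0.21 (-0.44 to 0.18), at percentile 1.14. CDF1 was at 7.40 and 2.28 FPKM, CCA1 at 2.44 and 0.84 FPKM, BOA at 1.87 and 4.12 FPKM and PRR3 at 35.6 and 21.3 FPKM. Markers of roots, which a rosette sample should hold little of, were lower as well, with all 8 below 0, 3 at least 2-fold lower and a median of -0.93 (-1.42 to -0.20), below all 10000 random lists. With TMM-scaled counts 5 were at least 2-fold lower. The iron transporter IRT1 was at 18.8 and 6.42 FPKM, the auxin carrier PIN2 at 10.09 and 3.87 FPKM, the root hair expansin EXPA7 at 5.59 and 1.95 FPKM and COBL9 at 4.07 and 1.57 FPKM. COR15A, COR15B, COR6.6, CBF1, SQP1 and FUM2 have fractional counts, divided with other genes. COR15B, BOA and EXPA7 overlap genes on the opposite strand.

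**Figure D3:**
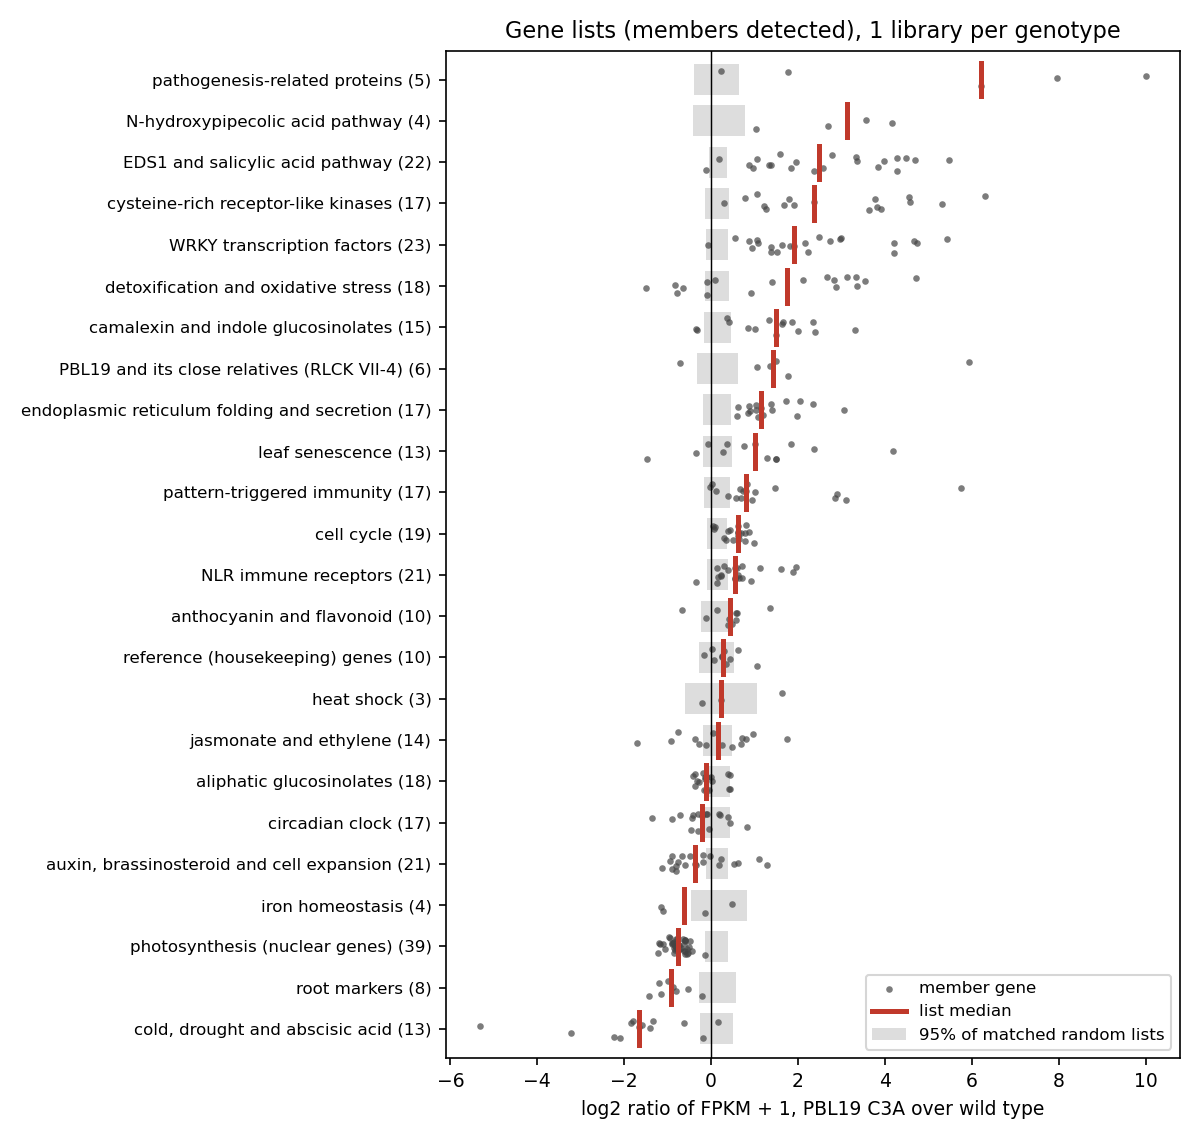
Log2 ratio of FPKM + 1, C3A over wild type (x axis), of the members (points) of each gene list with at least 3 detected members, with the list median in red and the range holding 95% of the medians of matched random lists in grey; numbers in brackets are detected members and there was 1 library per genotype. Pathogenesis-related proteins (median 6.21) lie at the top and cold, drought and abscisic acid genes (median -1.65) at the bottom.

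Nuclear photosynthesis genes were lower as a group. All 39 lay below 0, from -0.15 to -1.23, with a median log2 ratio of -0.77 (-0.85 to -0.61), below all 10000 random lists. Together they held 15.7% of wild type counts and 9.45% of C3A counts. At least 2-fold lower were 5 genes as deposited, 12 after rescaling to a median ratio of 1 and 13 with TMM-scaled counts. The light-harvesting proteins LHCB2.1 and LHCB1.2 were at 1733 and 5768 FPKM in the wild type and at 737 and 2539 FPKM in the C3A library. The small Rubisco subunit RBCS2B was at 2374 and 1026 FPKM, and PRK, the phosphoribulokinase of the Calvin cycle, was at 905 and 421 FPKM. All but PRK have fractional counts, shared with other genes, and PRK overlaps a gene on the opposite strand.

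Growth genes went in different directions. In the auxin, brassinosteroid and cell expansion list 15 of 21 genes lay below 0, and the median of -0.38 (-0.81 to 0.19) lay below all 10000 random lists. At least 2-fold higher were 2 genes and lower 1 gene as deposited, and 1 and 3 genes after rescaling to a median ratio of 1. XTH9, a cell wall enzyme, was at 44.5 and 111 FPKM, and PRE1 at 3.38 and 0.99 FPKM. The expansins EXPA1 and EXPA11 were at 64.6 and 46.7 FPKM in the wild type and at 139 and 23.9 FPKM in the C3A library. EXPA1 was at a log2 ratio of 1.1 as deposited and 0.95 after rescaling to a median ratio of 1. Cell cycle genes had a median of 0.62 (0.34 to 0.79), above 9999 random lists, and all 19 lay above 0 as deposited and 16 after that rescaling, but none reached 2-fold on the FPKM + 1 scale. KNOLLE, the syntaxin of dividing cells, was at 9.55 and 20.07 FPKM, CYCB1-1 at 2.30 and 5.04 FPKM, PCNA1 at 9.62 and 17.7 FPKM and CDKB2-1 at 12.3 and 22.01 FPKM. KNOLLE and CDKB2-1 overlap genes on the opposite strand.

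Several other lists differed little or held few detected genes. Aliphatic glucosinolate genes had no member past 2-fold among 18 and a median of -0.12 (-0.28 to 0.01), at percentile 2.19. GSTU20 was at 163 and 222 FPKM, SUR1 at 60.6 and 82.4 FPKM, BCAT4 at 99.8 and 133 FPKM and the regulator MYB28 at 45.0 and 33.2 FPKM. Anthocyanin and flavonoid genes had 1 of 10 at least 2-fold higher and a median of 0.45 (-0.13 to 0.59), at percentile 95.9. The anthocyanin carrier GSTF12 was at 2.31 and 7.5 FPKM, F3H at 26.5 and 16.4 FPKM, LDOX at 6.25 and 9.92 FPKM and UGT75C1 at 6.88 and 10.8 FPKM. In the iron list 2 of 4 genes were at least 2-fold lower, with a median of -0.62 (-1.16 to 0.49) at percentile 0.87, in libraries in which all 8 root markers, the iron transporter IRT1 among them, also lay below 0. The regulators bHLH39 and bHLH101 were at 2.15 and 2.4 FPKM in the wild type and at 0.41 and 0.59 FPKM in the C3A library. The ferritin FER1 was at 77.4 and 109 FPKM and the reductase FRO3 at 16.6 and 14.99 FPKM. Of 3 detected heat shock genes HSP90.1 was higher, at 1.89 and 8.01 FPKM, while HSP101 was at 1.81 and 2.30 FPKM and HSP18.2 at 1.73 and 1.38 FPKM. Their median was 0.23 (-0.20 to 1.64) at percentile 66.4. Of the flower markers FUL was at 1.36 and 2.08 FPKM and SHP1 at 0.54 and 1.27 FPKM. The others lay under 1 FPKM in both libraries, and 0 seed markers were detected at 1 FPKM. In these lists BCAT4, GSTF12, F3H, UGT75C1, bHLH101, FER1, FRO3, HSP101 and SHP1 overlap genes on the opposite strand.

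Housekeeping genes, the controls of the comparison, had a median of 0.28 (0.02 to 0.62) at percentile 70.0 as deposited and 0.13 after rescaling to a median ratio of 1, with 9 of 10 above 0 as deposited and 7 after rescaling. UBQ10 was at 813 and 1690 FPKM, and its log2 ratio of 1.05 was 0.91 after that rescaling. UBQ5 was at 199 and 307 FPKM, EF1ALPHA at 673 and 916 FPKM and ACT8 at 164 and 208 FPKM, and all 4 have fractional counts, shared with other genes. EF1ALPHA also overlaps a gene on the opposite strand.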

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

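The restrictions to genes with whole counts and to genes of at least 500 bases, and the PBL19 subgroup without PBL19 and PBL20, were chosen after seeing the data, and the other alternatives before. Of the list medians whose interval excluded 0 (23 of 39), 0 changed sign with either pseudocount, either filter or any of the 3 scalings. The number of higher genes ranged from 416 to 2067 and that of lower genes from 57 to 911. A pseudocount of 5 gave 735 higher and 243 lower genes, a pseudocount of 0.1 gave 911 lower, a 4-fold threshold gave 416 and 57, and TMM-scaled counts gave 868 lower. A larger pseudocount shrinks the ratios of low genes and a higher threshold admits fewer genes by construction. Rescaling FPKM applies 1 factor to a library, so it too moves the ratios by construction, from a median gene of 0.14 to 0.01. TMM-scaled counts also change the measure, and their cause was not tested beyond the shift of the median gene. With whole counts only, 1245 of 16808 genes were higher and 436 lower, and with genes of at least 500 bases 1470 of 19081 and 529. With a pseudocount of 5, the log2 ratio of PBL19 was 5.33 and the medians were 1.29 for the WRKY list, 0.25 for NBS-LRR proteins, 0.75 for the CRK family, 0.35 for receptor like proteins and 0.45 for ribosomal proteins. With a pseudocount of 0.1, the medians were 4.55 for N-hydroxypipecolic acid, 4.53 for the CRK list and 1.43 for receptor like proteins. Under rescaling to a median ratio of 1, rescaling without the 100 most abundant genes, and TMM, in that order, photosynthesis was at -0.92, -0.93 and -0.93, ribosomal proteins at 0.34, 0.34 and 0.33, histones at 0.59, 0.58 and 0.57, cytochromes P450 at -0.092, -0.096 and -0.10, and chloroplast-encoded genes at -0.54, -0.55 and -0.55. Mitochondria-encoded genes were at 0.028 with TMM. Besides PBL19, 116 genes are named one by one and have a counting interval, carried over here to the log2 ratio of FPKM + 1. With another pseudocount, 131 values lay within that interval and 101 outside, and with another scaling 265 lay within it and 83 outside. The median of the PBL19 subgroup was 1.36 without PBL19 and 1.21 without PBL20 as well. Matching random lists on the wild type level moved percentiles most for mitochondria-encoded genes (82.4 to 17.3), SAUR genes (39.1 to 8.79), plant defensins (32.6 to 10.7), housekeeping genes (70.0 to 86.5) and jasmonate and ethylene (46.7 to 30.4), and aliphatic glucosinolates moved from 2.19 to 7.30. No paired analysis was possible because there was 1 library per genotype, and leaving out a library was not possible for the same reason. Depth limits genes with few counts: 97 of the higher genes were unlisted in the wild type and 21 of the lower ones in the C3A library.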

Other observations

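The test on the clock genes and the test on runs of neighbouring genes were chosen after their results had been seen, and the requirement that the clock tests hold with both scalings was added then too. The second root list, the second clock list and the test on PBL20 were written down before their values were looked at. Families named by reference description were fixed before the data were examined.

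Larger families gave a wider view than the lists, but several of them, such as the WRKY and cysteine-rich receptor-like kinase families, also hold list members. The values of those families therefore repeat part of the list results. Of 61 WRKY family members 27 were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.72 (0.36 to 1.39). The cysteine-rich receptor-like kinase family had 21 of 33 higher and 1 lower, with a median of 1.21 (0.78 to 2.36), receptor like proteins had 22 of 45 higher and 1 lower, with a median of 0.96 (0.54 to 1.29), and NBS-LRR disease resistance proteins had 22 of 122 higher and 2 lower, with a median of 0.48 (0.30 to 0.56). Ribosomal proteins were mostly higher, ranging from -1.02 to 1.65, with 280 of 313 above 0, 5 at least 2-fold higher, 1 lower and a median of 0.49 (0.46 to 0.52), and 255 of 314 lay above 0 and 2 were at least 2-fold higher after rescaling to a median ratio of 1. Histones had 42 of 46 above 0, 5 at least 2-fold higher, 1 lower and a median of 0.73 (0.63 to 0.77), and 42 lay above 0 and 2 were at least 2-fold higher after that rescaling. The medians of these 6 families lay above all 10000 matched random lists. Heat shock proteins had 5 of 34 higher, 0 lower and a median of 0.38 (0.23 to 0.59). Expansins had 1 of 22 higher, 4 lower and a median of -0.33 (-0.94 to 0.40). Genes encoded in the chloroplast were lower, with 60 of 79 below 0, a median of -0.40 (-0.48 to -0.17), 1 gene at least 2-fold higher and 3 lower (8 lower after rescaling). Those encoded in mitochondria had 27 of 38 above 0, 4 at least 2-fold higher and a median of 0.23 (0.05 to 0.48) at percentile 82.4, with 21 of 37 above 0 after rescaling. With TMM-scaled counts, 11 of 22 lay above 0 and 0 were at least 2-fold higher. Mitochondria-encoded genes held only 0.0059% of wild type and 0.0075% of C3A counts, so their ratios rest on few counts. Their percentile was 17.3 against random lists matched on the wild type level, so they do not stand apart.

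Other families had many genes on both sides of 0. Glutathione S-transferases had 10 of 49 higher and 3 lower (median 0.18), although GSTF2, GSTF6 and GSTF7 were among the most different genes of their list. Cytochromes P450 had 25 of 160 higher and 15 lower (median 0.04), UDP-glucosyltransferases 12 of 108 and 5 (median 0.03), SAUR genes 9 of 49 and 0 (median 0.10), and plant defensins 3 of 13 and 4 (median 0.05). The medians of these last 4 families changed sign in at least 1 alternative, so these medians have no direction against 0. Against matched random lists, cytochromes P450 lay at percentile 2.98, UDP-glucosyltransferases at 2.41, SAUR genes at 39.1 and plant defensins at 32.6. The SAUR genes past 2-fold were all higher, 9 as deposited and 6 after rescaling to a median ratio of 1.

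Genes higher in the C3A library lay next to each other more often than in shuffled gene orders. Among 19410 genes in chromosomal order, 32 windows of 10 neighbouring genes held at least 7 genes that were 2-fold higher, against at most 3 in 1000 shuffled orders, and the fullest window held 10 against 8. They formed 5 blocks, located here on TAIR10.1. The shuffled orders treat genes as independent, while several blocks hold related genes side by side, which were not collapsed. The comparison therefore does not tell a pattern of gene position from related genes that differ together. The block with the largest median, 4.98, lies on chromosome 4 at 11840119 to 11860426, from AT4G22467 to AT4G22520, where all 12 genes were higher and 7 are described as lipid-transfer proteins, but 11 overlap a neighbour, and whether counting used strand was not given in the sources used here. A second block on chromosome 4, at 12117491 to 12177576, runs from CRK5 to CRK20 and had 13 of 17 genes higher and 1 lower, 15 of the 17 described as cysteine-rich receptor kinases, several with fractional, shared counts and 6 overlapping a neighbour. The lower gene, AT4G23271, rests on 1 count in the wild type and 0 in the C3A library. CRK20, among the higher ones, was at a log2 ratio of 1.06 from 0.15 and 26.44 counts. Many genes of this block are also in the list and the family of cysteine-rich receptor-like kinases, so the block repeats part of those results. The other blocks were AT1G65481 to AT1G65510 on chromosome 1 at 24340736 to 24360081 (7 of 7 higher), AT5G44567 to AT5G44585 on chromosome 5 at 17953282 to 17986431 (9 of 10), and AT5G52640 to AT5G52810 on chromosome 5 at 21352557 to 21400686 (8 of 12). The members of these 3 blocks do not overlap each other, but several rest on few or no wild type counts. AT1G65481, AT1G65483, AT5G52720, AT5G52730 and AT5G52770 were unlisted in the wild type, and AT1G65484 and AT5G52740 had 1 count each there. Other annotated genes overlap 3 members of the AT5G44567 block and, in the AT5G52640 block, SARD4, whose counts are fractional. The same block holds AT5G52760, of a copper transport protein family, at 0.92 and 95.1 FPKM. The genes named here were chosen after their values were seen.

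Cold and abscisic acid genes were lower in the C3A library, and a harvest at another time of day is a candidate explanation besides the genotype. A large shift should move clock genes and clock-controlled genes of a second list. On the FPKM + 1 scale, 1 of 17 clock genes differed at least 2-fold (upper 95% bound of the share 28.7%). Of the second list 1 of 16 did (RVE2, at 13.0 and 5.76 FPKM, upper bound 30.2%, median log2 ratio 0.03). With TMM-scaled counts 3 of 18 and 3 of 16 did, with upper bounds of 41.4% and 45.6%, so a share of 1 in 3, which the explanation was taken to need, was not excluded. The limit set for excluding it, fewer than 1 in 6, was met as deposited, but the upper bounds lay above that limit. These upper bounds treat the genes of a list as independent and do not cover differences between harvests or libraries. Time of day and genotype cannot be told apart for these genes, because each genotype has 1 library and harvest times were not given in the sources used here.

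Root markers were lower in the C3A library, and more root tissue carried into the wild type sample is a candidate explanation. A second list of 16 root-expressed genes had a median of -1.19 (-1.44 to -0.46), with all 16 below 0 and 9 at least 2-fold lower, as carry-over would give. THAS1, of thalianol synthesis, was at 78.5 and 28.3 FPKM and PRP3 at 27.5 and 6.03 FPKM. The most abundant root genes differed little, PYK10 at 1492 and 1318 FPKM and JAL30 at 455 and 380 FPKM, which a single factor for root tissue does not give unless rosettes express them too. A lower expression of root-type genes in the C3A line itself was not tested and stays open.

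PBL20 was higher in the C3A library, and reads of the abundant PBL19 transcript assigned to PBL20 are a candidate explanation. The transcripts share 4 stretches of 31 bases, within a longest shared stretch of 34 bases, which is shorter than the 150 bp reads, and the PBL20 counts were whole in both libraries. No stretch of 150 bases is shared, so an untrimmed read of 1 transcript does not match the other exactly along its length. The bound set for excluding the explanation, no shared stretch of 31 bases, was not met, so stray PBL19 reads were not excluded for these 38 counts.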
